A study of Mus musculus with 24 samples.

How the data were processed

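The deposited files held gene abundances from StringTie, per the file headers, with 3 lane files for each of 24 mice, 72 in all. Per the labels, the authors made libraries with the TruSeq Stranded Total RNA kit and Ribo-Zero Gold after DNase I treatment, kept RNA with a RIN over 8, sequenced paired ends on an Illumina HiSeq, aligned to mm10 with HISAT and assembled with StringTie. Tool versions, mapping rates and read trimming are not given in the sources used here. Per the file headers each gene has a coverage, an FPKM and a TPM. The deposited FPKM behaved as an abundance per length and depth. The deposited TPM was FPKM times 1 constant per file. Its assembled loci summed to 1000000 and the reference genes came on top with sums of 251620 to 389306, so TPM was treated as a relative signal. The deposited coverage was read as mean depth per base and used to recover aligned bases. Read counts were not used here, so that edgeR and DESeq2 were not applied and limma was the only tool for genes.

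Every file listed the same 24421 reference gene IDs in 24655 records, 157 of the IDs having several, which were added. A lane file was called complete when each of chromosomes 1 to 19 and X had at least 80% of the median number of genes above 0 over the files. The rule had been written for listed genes and was applied to genes above 0, because every file lists all IDs. Of 72 lane files 51 were complete and 21 were not. The complete files numbered 1 in 6 mice, 2 in 9 and 3 in 9. Lane files are repeat runs of 1 library and were never treated as replicates: they were scaled by the median of ratios over 15345 genes (factors 0.788 to 1.17) and the complete ones averaged. Pairs of lane files had a median r across genes of 0.994 within a mouse, 0.989 within a group and 0.976 between strains. The depth was 2.83 to 9.86 aligned gigabases per mouse and 0.581 to 3.41 per complete file. Counting error could not be computed without counts. No mitochondrial reference genes were in the files.

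Genes with TPM above 1 in at least 4 mice were kept, 13892. The log2 of scaled TPM plus 1 was fitted with 6 group means over 24 mice by limma, with empirical Bayes moderation, trend and robust settings. A gene passed at a Benjamini-Hochberg adjusted p < 0.05, two-sided. The median SE was 0.0784 log2 for a difference of 4 against 4 mice, 0.0453 for the average over strains and 0.111 for a difference between strains in response. The interaction was an F test with 2 degrees of freedom. Gene lists were fixed before the data were examined and tested with camera of limma at a preset correlation of 0.01, and also with an estimated correlation and with fry. Fry tests whether the genes of a list move, on balance, in 1 direction, and its mixed form whether they change in either direction. Of 39 lists 38 had the 3 tested members needed. List scores are the mean log2(scaled TPM + 1) of a list per mouse and were compared by exact permutation, two-sided, in 114 tests over lists and strains, of which 0 passed (smallest adjusted p = 0.652). An exact test of 4 against 4 cannot go below p = 0.0286, and the ranges of such groups lie apart by chance in 2.86% of genes. Over 114 tests a pass at that floor would need many scores to reach it together. Relations over 10 or more mice used 100000 permutations.

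Genes were named by a rule written in advance. In a comparison it takes up to 12 genes each way past the threshold by largest log2 difference with group ranges apart, 8 each way for strain comparisons. Where fewer than 10 pass it takes the 10 smallest p, said not to pass. It adds up to 4 members with the smallest p of a list described, and the 12 appetite and fructose genes. Snord123, Mirlet7b, Peg3os, Lars2 and the pre-ribosomal RNA group lie outside this rule and were chosen after their values were seen. Unnamed predicted genes were counted but not named. A gene that the rule takes in the C57BL/6J fructose comparison is not reported here. Places of genes are those of the files, on mm10.

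The animal numbers in the titles of the labels recur between strains. In the C57BL/6J and DBA/2J water mice numbered 2, 3 and 4 the same-number pairs had r of 0.226, 0.126 and 0.355 across genes after group means were removed, against −0.115 to 0.0499 for other pairs, so the number was treated as a possible pairing. With it as a replicate block 2336 genes passed in DBA/2J against C57BL/6J in place of 2738.

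The fit was tested on simulated data with the spread of these mice, 200 changed genes among 13892 in each of 5 runs. It recovered 85.7%, 98.2% and 100% of genes changed by a log2 of 0.5, 1 and 2, and 6.24% of its calls were unchanged genes. A list moved by 0.3 was called in 5 of 5 runs and 0 other lists were, with genes simulated as independent. Simulated genes lack the correlation of real ones, so this gives no error rate for the lists. R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.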

Results

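RNA was measured in the hypothalamus of 24 male mice of the inbred strains C57BL/6J, DBA/2J and FVB/NJ. In each strain 4 mice drank 8% (w/v) fructose for 14 weeks from 7 weeks of age and 4 drank plain water. Values are scaled TPM (relative transcript abundance, scaled to a common median between mice) as mean ± SD over 4 mice per group, unless another n is given, and log2 differences are fructose minus water. Genes known to differ between these strains were read first. Gabra2 (mm10, chromosome 5, 70961057 to 71095849), a GABA receptor subunit that C57BL/6J expresses at a low level, averaged 7.70 ± 0.813 in C57BL/6J (n = 8), 29.9 ± 3.07 in DBA/2J (n = 8) and 32.1 ± 2.13 in FVB/NJ (n = 8). Nnt (chromosome 13, 119334317 to 119409257), the mitochondrial transhydrogenase that carries a deletion in C57BL/6J, averaged 4.79 ± 0.5, 7.86 ± 0.680 and 9.60 ± 0.618 (n = 8 each). Glo1 (chromosome 17, 30592862 to 30612659), a glyoxalase gene, was taken beforehand to be duplicated in DBA/2J and FVB/NJ. It averaged 96.2 ± 2.40 in DBA/2J, 52.1 ± 1.74 in C57BL/6J and 42.1 ± 2.12 in FVB/NJ (n = 8 each). It was therefore not higher in FVB/NJ than in C57BL/6J, against that expectation. Gpnmb (chromosome 6, 49036518 to 49058182), a melanosome glycoprotein truncated in DBA/2J, was at most 0.0359 in the 8 DBA/2J mice and at least 0.122 in the other 16. Klrd1, a natural killer cell receptor deleted in DBA/2J, was listed at 0 in every DBA/2J mouse but reached only 0.0676 and 0.0856 in the other strains, so it told no strain apart. In a principal component analysis the first 2 components carried 32.1% and 20.8% of the variance and held the 3 strains apart.

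**Figure D1:**
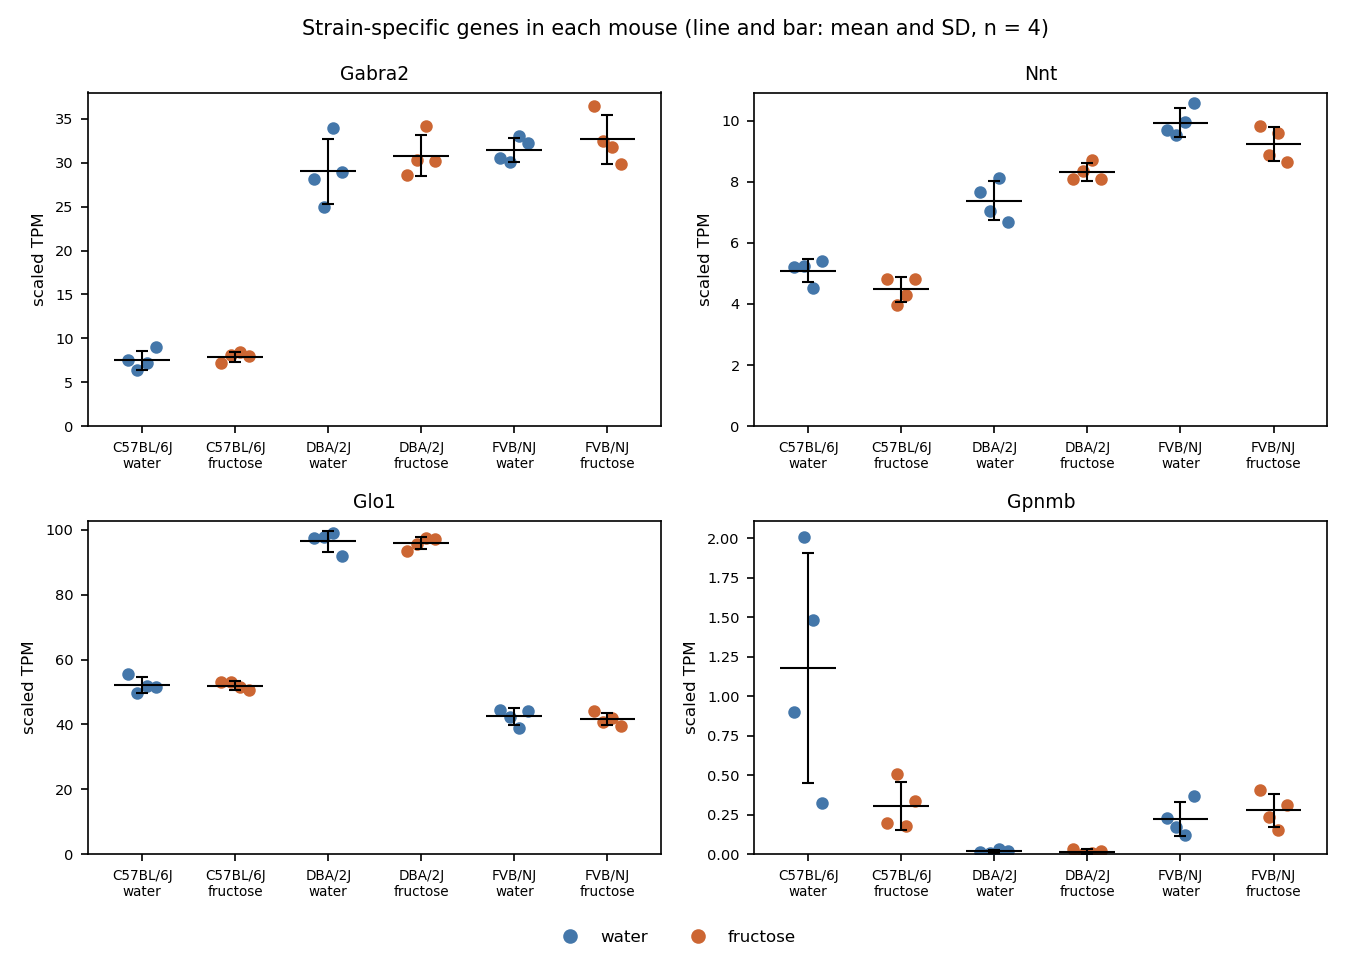
Scaled TPM of Gabra2, Nnt, Glo1 and Gpnmb for each mouse (points, blue for water and orange for fructose) in the 3 strains, with line and bar for the mean and SD of 4 mice. Gabra2 runs from 6.42 to 8.99 in C57BL/6J and from 25.0 to 36.5 in the other strains, and Glo1 from 91.8 to 99.0 in DBA/2J and from 38.9 to 55.4 in the others.

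In C57BL/6J, markers of the meninges, the membranes around the brain, were lower as a group in fructose mice. All 15 tested were lower, by a median log2 difference of −0.84 (camera adjusted p = 5.02e-10, adjusted p = 0.557 with an estimated correlation). Among them Slc22a6, an organic anion transporter, averaged 0.351 ± 0.163 on fructose and 1.98 ± 1.77 on water, and Slc13a3, a dicarboxylate transporter, 2.78 ± 0.173 and 6.54 ± 3.91. Of the extracellular matrix genes 25 of 26 also had lower values (median −0.29, adjusted p = 4.39e-08, and 0.557 with an estimated correlation). They share Dcn and Ogn, proteoglycans of 5.68 ± 1.09 against 10.8 ± 5.70 and 1.52 ± 0.592 against 5.38 ± 4.62, with the meninges list. Fn1, fibronectin, averaged 3.21 ± 0.863 on fructose and 5.74 ± 3.09 on water, and Ctgf, a matrix-bound growth factor, 3.57 ± 0.917 and 6.03 ± 2.26. An exact test on the mean of the list did not tell the meninges scores of the groups apart (exact p = 0.114, n = 4 per group). The score was 1.93 ± 0.217 on fructose and 2.69 ± 0.766 on water.

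Blood vessel and microglia markers were lower in C57BL/6J fructose mice as well. Markers of endothelial cells (12 of 14 lower, median −0.13, adjusted p = 0.0021), of pericytes and smooth muscle (8 of 10, −0.18, adjusted p = 0.00773), of microglia and macrophages (13 of 14, −0.10, adjusted p = 0.000556) and of oligodendrocyte precursors (10 of 11, −0.11, adjusted p = 0.0364) each gave adjusted p = 0.557 with an estimated correlation. Cldn5, a tight junction protein of the blood-brain barrier, averaged 13.7 ± 1.23 on fructose and 16.6 ± 0.993 on water, and Ctss, a microglial protease, 48.2 ± 2.53 and 54.9 ± 4.91. All 16 markers of the thalamus were lower (median −0.40, adjusted p = 3e-07, and 0.557 with an estimated correlation), among them Tnnt1, a troponin, at 5.46 ± 3.16 and 10.7 ± 3.57. Heat shock genes were lower by a median of 0.071 (12 of 13, adjusted p = 0.0473, and 0.673 with an estimated correlation), with Hspb1, a small heat shock protein, at 6.83 ± 1.06 and 9.48 ± 2.41. The heat shock call was lost without C57BL/6J water 4 (10 of 13 lower, median −0.0375, adjusted p = 0.265). It was also lost without fructose 10, fructose 12 or water 1 (adjusted p = 0.123, 0.0821 and 0.169).

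Peptide and ribosomal protein transcripts were higher in C57BL/6J fructose mice. Of the list of posterior pituitary and reproductive neuropeptides 9 of 10 had higher values (median 0.22, adjusted p = 0.0141, and 0.557 with an estimated correlation). The call was lost without C57BL/6J water 1 (7 of 10 higher, median 0.106, adjusted p = 0.154) or fructose 10 (median 0.213, adjusted p = 0.0641). Tac2, the neurokinin B precursor, averaged 20.8 ± 1.07 on fructose and 16.1 ± 0.939 on water, and Oxt, oxytocin, 400.1 ± 39.7 and 308 ± 24.0. Appetite and energy balance neuropeptides (19 of 22 higher, median 0.13) and markers of hypothalamic regions (18 of 23 higher, median 0.13) both passed at adjusted p = 0.042, and both gave 0.673 with an estimated correlation. Dlx2, a transcription factor of hypothalamic GABA neurons, averaged 1.37 ± 0.0980 and 1.04 ± 0.157. In the same mice the thalamus score was 3.77 on fructose and 4.24 on water, and the hypothalamic region score 1.65 and 1.56. Over the 16 C57BL/6J and FVB/NJ mice, with group means removed, these scores were opposed (r −0.723). A dissection with less thalamus and more hypothalamus was therefore not told apart from an effect of fructose on the peptides. Cytosolic ribosomal protein genes were higher in 36 of 38 cases by a median of 0.087 (adjusted p = 1.11e-07, and 0.557 with an estimated correlation), with a median of −0.016 under TPM as deposited, which moved all genes by a median of −0.0876. Rps19 averaged 242 ± 4.36 and 214 ± 9.89. Ribosomal protein genes have many near-identical copies in the genome, which makes their read assignment uncertain.

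No single gene passed adjusted p < 0.05 for fructose in C57BL/6J (0 of 13892 tested by limma, with 658 at unadjusted p < 0.05 where 695 are expected by chance). The smallest adjusted p, 0.69, belonged to Lgals3 (chromosome 14, 47373860 to 47386167), a galectin of activated microglia and macrophages, at 0.612 ± 0.108 on fructose and 1.55 ± 0.480 on water (log2 difference −0.64, SE 0.128). It passed with array weights (adjusted p = 0.0341) and without C57BL/6J water 4 (adjusted p = 0.0257), over a range of 0.0257 to 0.998 in 38 alternatives. Spp1 (chromosome 5, 104435111 to 104441053), osteopontin, averaged 4.56 ± 0.597 and 14.2 ± 8.69 (log2 difference −1.24, SE 0.306, adjusted p = 0.901). It passed without C57BL/6J water 4 (adjusted p = 0.027, range 0.027 to 1 over 39 alternatives), which gave a count of 2 genes, and with the plain mean of all 3 lane files, chosen after seeing the data and outside that range (adjusted p = 0.00367). Among the others of the 10 smallest p, none of which passed, was Commd9, a copper metabolism domain protein (25.7 ± 0.792 against 19.4 ± 4.43, adjusted p = 0.901). Camera called 12 of 38 lists, 4 higher and 8 lower, and 0 with an estimated correlation or with fry (smallest adjusted p 0.547, and 0.905 for its mixed form). As many lists were called in 8 of 35 splits of the C57BL/6J mice, the real one included and described below. Without C57BL/6J fructose 10 the count of lists was 7. Only the meninges, thalamus, extracellular matrix and ribosomal protein lists stayed called without any 1 mouse of the strain (largest adjusted p = 0.000245, 0.00415, 0.00331 and 0.0001). Without C57BL/6J water 2 the microglia, endothelial and pericyte lists were not called (medians −0.0679, −0.0786 and −0.113, adjusted p = 0.0775, 0.108 and 0.266). Nor was the oligodendrocyte precursor list (median −0.0529, adjusted p = 0.142), a call also lost without fructose 10, fructose 12 or water 1 (adjusted p = 0.0762, 0.0808 and 0.0599). Water 2 also stood apart in assembled loci without a strand, as given below. Adjusted over the list alone, 1 member of the lists called passed, Tac2.

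In DBA/2J, the gene with the smallest p was Stab2 (chromosome 10, 86841210 to 87007942), a hyaluronan scavenger receptor of sinusoidal endothelium. It averaged 9.22 ± 3.88 on fructose and 3.92 ± 0.848 on water (log2 difference 0.99, SE 0.166, limma adjusted p = 0.0677), against 0.282 and 0.317 in C57BL/6J and 0.0941 and 0.0556 in FVB/NJ. Stab2 did not pass over all 13892 genes. It passed with TPM as deposited (adjusted p = 0.000515), with the best lane file of each mouse (0.0341) and without DBA/2J fructose 12 (0.000797), fructose 9 (0.0232) or water 2 (0.0448), over a range of 0.000515 to 0.999 in 39 alternatives, and with the plain mean of all 3 lane files, chosen after seeing the data and outside that range (adjusted p = 3.39e-06). No other gene of this comparison was under adjusted p = 0.987. Clk1, a splicing kinase, averaged 25.1 ± 3.14 and 35.2 ± 6.73, and Rab30, a Golgi GTPase, 7.22 on fructose and 8.87 on water, both within the 10 smallest p. The count was 0 genes, with 545 at unadjusted p < 0.05 where 695 are expected.

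Glucocorticoid responsive and immediate early genes were lower in DBA/2J fructose mice. All 14 glucocorticoid responsive genes had lower values (median −0.29, adjusted p = 8.37e-07, and 0.821 with an estimated correlation), among them Fkbp5, a co-chaperone of the glucocorticoid receptor, at 7.40 ± 1.56 on fructose and 10.6 ± 4.20 on water. Plin4, a lipid droplet protein, averaged 4.60 ± 3.27 and 10.6 ± 6.95. The glucocorticoid call was lost without DBA/2J water 5 (11 of 14 lower, median −0.17, adjusted p = 0.0511, range 1.07e-10 to 0.0511 without 1 DBA/2J mouse). Immediate early genes, which neuronal activity induces, were lower in 21 of 23 cases (median −0.14, adjusted p = 5.39e-06, and 0.821 with an estimated correlation). Fos averaged 5.53 ± 1.09 and 11.5 ± 3.60, Egr1 1.74 ± 0.427 and 3.40 ± 0.687, and Dusp6, a phosphatase of ERK, 8.15 ± 0.624 and 10.0 ± 0.529. The mean of the immediate early list was 2.02 ± 0.0613 on fructose and 2.24 ± 0.0887 on water with no overlap between mice (exact p = 0.0286, n = 4 per group), which is the smallest p that 4 against 4 can give. In C57BL/6J 4 list scores gave the same exact p = 0.0286 (n = 4 per group): those of posterior pituitary and reproductive neuropeptides, ribosomal proteins, inflammation and neurons, of which the last 2 were not called by camera. For the glucocorticoid score the exact p was 0.286, and none of the list scores passed adjustment over 114 tests (smallest adjusted p = 0.652). With the floor of 0.0286 a pass would have needed many more scores at that floor. The lack of a pass is therefore no evidence against a list. Circadian clock genes were lower in 16 of 20 cases (median −0.077, adjusted p = 0.0094, and 0.821 with an estimated correlation), with Per1 at 4.90 and 6.13. The clock call was lost without DBA/2J water 5, water 3 or fructose 12 (medians −0.061, −0.0834 and −0.0474, adjusted p = 0.0511, 0.16 and 0.07). Immediate early genes stayed called without any 1 DBA/2J mouse (adjusted p from 1.75e-08 to 0.00247).

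Several metabolic and peptide lists were also called in DBA/2J. In 19 of 35 splits of the DBA/2J mice, the real one included and described below, camera called as many lists. Insulin signalling genes were lower in 17 of 21 cases (median −0.10, adjusted p = 0.0028), with Irs1, an insulin receptor substrate, at 3.66 ± 0.208 and 4.37 ± 0.367. Cholesterol synthesis genes were lower in 17 of 23 cases (median −0.047, adjusted p = 0.0119), with a median of 0.031 under TPM as deposited, which moved all genes by a median of 0.0661. The cholesterol call was lost without DBA/2J water 3 (median −0.0209, adjusted p = 0.465). It was also lost without fructose 10, fructose 12 or water 4 (adjusted p = 0.0695, 0.0579 and 0.0758). Unfolded protein response genes were higher in 15 of 21 cases (median 0.093, adjusted p = 0.0249), with Calr, a chaperone of the endoplasmic reticulum, at 157 ± 7.14 and 134 ± 6.92 and Hspa5 at 174 ± 10.3 and 149.9 ± 27.8. Markers of hypothalamic regions (20 of 23 higher, median 0.12, adjusted p = 0.00967) and appetite neuropeptides (18 of 22 higher, median 0.10, adjusted p = 0.021) were higher, and these 5 lists gave adjusted p = 0.885 with an estimated correlation. Agrp, which drives feeding, averaged 5.19 ± 1.25 and 3.49 ± 2.42. Thalamus markers were lower in 15 of 16 cases (median −0.24, adjusted p = 0.0144) and ribosomal protein genes higher in 32 of 38 (median 0.034, adjusted p = 0.0317), both with adjusted p = 0.892 with an estimated correlation. Camera thus called 10 of 38 lists, 4 higher and 6 lower, and 0 with an estimated correlation or with fry (smallest adjusted p 0.887, mixed 0.993). The count rested on single mice: it was 2 without DBA/2J water 5, 4 without water 3 and 6 without fructose 12. Without water 5 cholesterol synthesis and immediate early genes were left. The insulin signalling list then had a median of −0.018 (adjusted p = 0.476), the thalamus, hypothalamic region and appetite lists −0.0064, −0.003 and 0.024 (adjusted p = 0.912, 0.912 and 0.979), and ribosomal protein genes a reversed median of −0.029 (adjusted p = 0.0667). Without the 3 doubted libraries, a setting chosen after seeing the data, the insulin median was −0.033 (adjusted p = 0.204). Of the 10 lists only the immediate early list stayed called without any 1 DBA/2J mouse. Adjusted over the list alone, 1 member of the lists called passed, Calr.

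In FVB/NJ, immediate early genes were lower on fructose in 21 of 23 cases (median −0.19, adjusted p = 2.45e-08, and 0.914 with an estimated correlation). Ier2, an immediate early regulator, averaged 1.13 ± 0.0824 on fructose and 1.86 ± 0.336 on water, Cyr61, a secreted matrix protein, 1 ± 0.238 and 1.5 ± 0.170, and Klf2, an endothelial transcription factor, 2.86 ± 0.503 and 4.42 ± 1.31. Erythrocyte markers were higher (median 0.86, 5 of 7, adjusted p = 0.00031, and 0.914 with an estimated correlation), through the globin genes Hba-a1 at 686 ± 243 and 329.5 ± 170, Hbb-bs at 709 ± 296 and 349 ± 145 and Hbb-bt at 242 ± 99.9 and 122 ± 50.5. The globin genes are near-identical copies, so that the division of reads among them is uncertain. Nuclear oxidative phosphorylation genes were lower in 32 of 33 cases by a small median of 0.049 (adjusted p = 0.00031, and 0.914 with an estimated correlation), as for Ndufa4 at 235 ± 7.39 and 253 ± 12.4. All 14 striatum markers were lower (median −0.25, adjusted p = 0.000429), among them Ppp1r1b, the dopamine-regulated phosphatase inhibitor, at 12.0 ± 6.87 and 21.0 ± 11.8, and all 15 meninges markers were lower (median −0.35, adjusted p = 0.0143). Both gave adjusted p = 0.914 with an estimated correlation. Endothelial markers (13 of 14 lower, median −0.09, adjusted p = 0.015), ribosomal protein genes (35 of 38 lower, median −0.047, adjusted p = 0.0232) and posterior pituitary and reproductive neuropeptides (7 of 10 higher, median 0.085, adjusted p = 0.0486) also gave 0.914 with an estimated correlation. Cldn5 averaged 17.4 ± 2.12 and 21.5 ± 1.73. The ribosomal protein call was lost without FVB/NJ fructose 6 (26 of 38 lower, median −0.0241, adjusted p = 0.565) or water 9 (median −0.0332, adjusted p = 0.245). The endothelial call was lost without FVB/NJ water 9 (median −0.0557, adjusted p = 0.245). It was also lost without fructose 10, fructose 12 or water 8 (adjusted p = 0.171, 0.0851 and 0.0607).

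No FVB/NJ gene passed for fructose (0 of 13892 by limma, every adjusted p = 1, with 577 at unadjusted p < 0.05). The smallest unadjusted p, 0.000614, belonged to Dtx2, a Notch pathway ubiquitin ligase, at 1.94 ± 0.148 and 2.67 ± 0.109. Dlk1, a Notch ligand of hypothalamic neurons, averaged 8.01 ± 0.945 on fructose and 5.70 ± 1.14 on water, and Astn1, a neuronal adhesion protein whose gene overlaps Mir488, 37.5 ± 0.980 and 31.5 ± 2.17. Camera called 8 of 38 lists, 2 higher and 6 lower, and 0 with an estimated correlation or with fry (smallest adjusted p 0.956, mixed 0.741). As many lists were called in 22 of 35 splits of the FVB/NJ mice, the real one included and described below. The count was 3 without FVB/NJ water 9 and 5 without FVB/NJ fructose 12. The immediate early, oxidative phosphorylation and erythrocyte lists stayed called without any 1 mouse of the strain (largest adjusted p = 0.00452, 0.0199 and 0.0216), whereas without FVB/NJ water 9 the meninges list had a median of −0.049 (adjusted p = 0.904) and the striatum list −0.14 (adjusted p = 0.179). The meninges call was also lost without fructose 5, fructose 10, fructose 12 or water 8 (adjusted p = 0.128, 0.0648, 0.321 and 0.268). The striatum call was also lost without water 1 (adjusted p = 0.0921). The posterior pituitary and reproductive list had a reversed median of −0.0092 without FVB/NJ water 2 (adjusted p = 0.543), and its call was also lost without fructose 5, fructose 12 or water 9 (adjusted p = 0.39, 0.0649 and 0.0741). Adjusted over the list alone, 8 members of the lists called passed: Cyr61, Ier2, Klf2 and Klf4 of the immediate early list and Hba-a1, Hba-a2, Hbb-bs and Hbb-bt of the erythrocyte list. The erythrocyte score was 7.10 ± 0.423 on fructose and 6.44 ± 0.414 on water (exact p = 0.0857, n = 4 per group), and the immediate early score gave exact p = 0.257.

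Averaged over the 3 strains, with 12 fructose and 12 water mice, immediate early genes and meninges markers had the smallest adjusted p. Immediate early genes were lower in 21 of 23 cases (median −0.15) and meninges markers in 15 of 15 (median −0.43), each at adjusted p = 1.65e-07, and at 0.563 with an estimated correlation. In C57BL/6J alone 13 of 23 immediate early genes were higher (median 0.0105, adjusted p = 0.695), so that this average came from the other strains. Among the former Dusp6 differed by −0.18 and Klf2 by −0.24, and among the latter Dcn by −0.37 and Ptgds, prostaglandin D synthase, by −0.60. Extracellular matrix (median −0.15, adjusted p = 4.8e-06), endothelial (−0.079, 0.00433) and clock genes (−0.054, 0.0256) were lower, and hypothalamic region markers (0.081, 0.00139) and posterior pituitary and reproductive neuropeptides (0.076, 0.00256) higher, all with adjusted p = 0.563 with an estimated correlation. Thalamus markers (−0.22, adjusted p = 2.25e-05), glucocorticoid responsive genes (−0.12, 0.00164) and pericyte markers (−0.084, 0.0256) were lower and appetite neuropeptides higher (0.084, 0.00847), with adjusted p = 0.627 with an estimated correlation. Ribosomal protein genes were higher (0.026, adjusted p = 0.00566, and 0.773 with an estimated correlation). Ribosomal protein genes were lower in FVB/NJ, as given above, and called there (median −0.047, adjusted p = 0.0232, and 0.914 with an estimated correlation). Other lists had another sign in 1 strain without a call there: 11 of 14 glucocorticoid responsive genes were higher in FVB/NJ (median 0.071, adjusted p = 0.501), and 8 of 14 endothelial markers higher in DBA/2J (median 0.023, adjusted p = 0.633). In FVB/NJ the thalamus median was −0.0035 although camera's direction was up (adjusted p = 0.949), and in DBA/2J the posterior pituitary and reproductive list had a median of −0.04 with camera's direction up (adjusted p = 0.634). No gene passed (0 of 13892 by limma, smallest adjusted p = 0.872, with 740 at unadjusted p < 0.05). The 10 smallest p included Pdlim1, a cytoskeletal adaptor, with log2 difference −0.30 (SE 0.0631), and Ctgf with −0.55 (SE 0.137), made of −0.59, −0.62 and −0.44 in C57BL/6J, DBA/2J and FVB/NJ. Larp1b, an RNA-binding protein with −0.16 (SE 0.0343), passed only with the meninges score as covariate, a setting chosen after seeing the data (adjusted p = 0.0353, range 0.0353 to 1 over 38 alternatives). Camera called 12 of 38 lists, 4 higher and 8 lower, and 0 with an estimated correlation or with fry (smallest adjusted p 0.578, mixed 0.901). As many lists were called in 33 of 100 regroupings of treatment within strain, the real one included. Adjusted over the list alone, 1 member of the lists called passed, Ctgf.

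**Figure D2:**
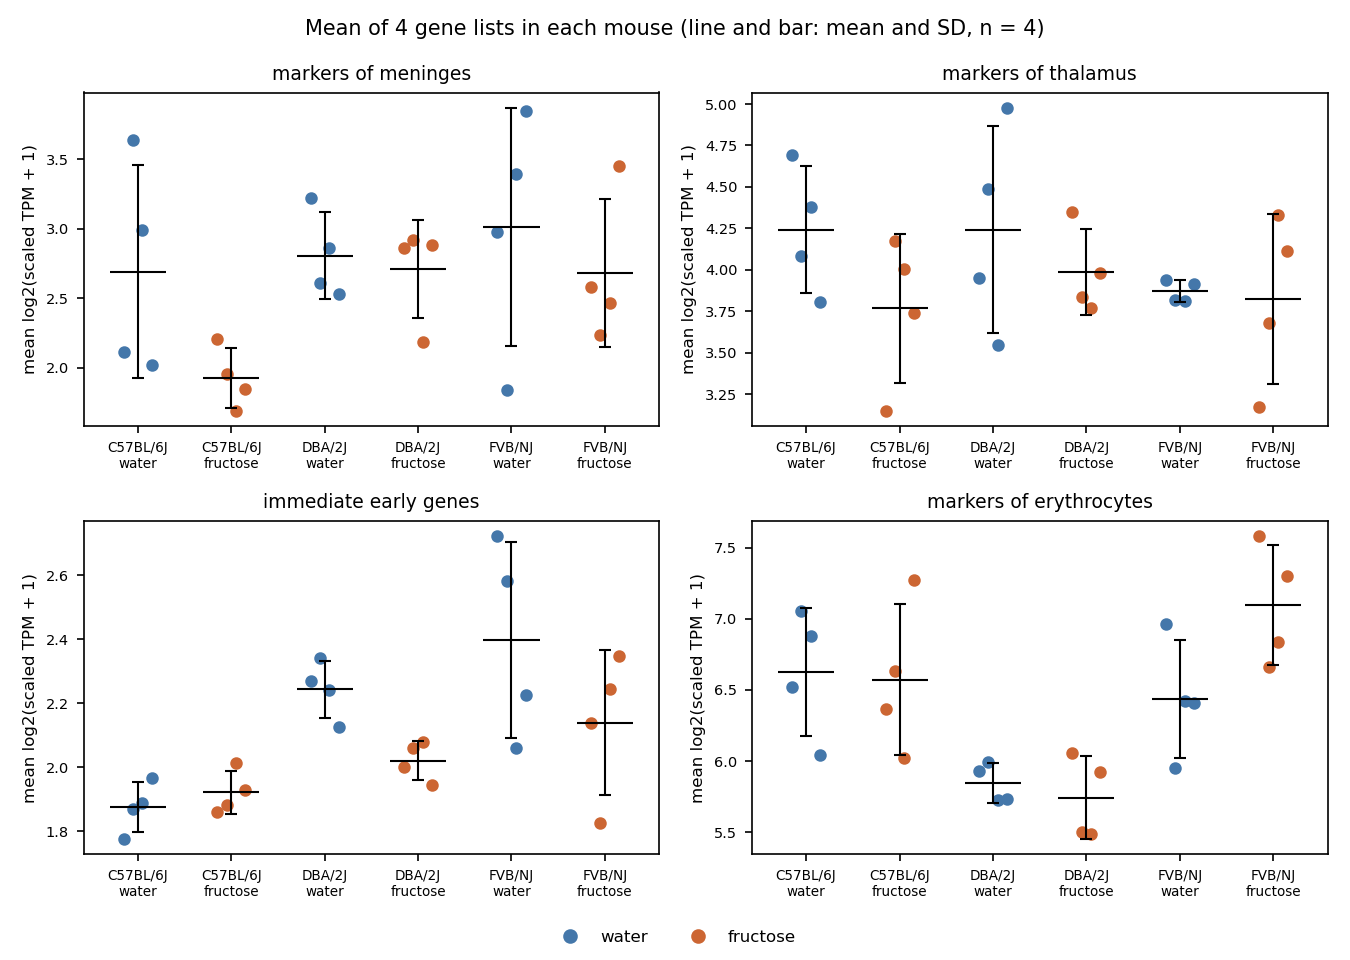
Mean log2(scaled TPM + 1) of the meninges, thalamus, immediate early and erythrocyte lists for each mouse (points, blue for water and orange for fructose) by strain, with line and bar for the mean and SD of 4 mice. In DBA/2J the immediate early score is 2.02 on fructose and 2.24 on water with no overlap, whereas the C57BL/6J meninges scores of 1.93 and 2.69 have overlapping mice.

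Whether strains differed in their response to fructose was tested directly. The genes with the smallest interaction p were Stab2, with log2 differences of −0.04, 0.99 and 0.05 in C57BL/6J, DBA/2J and FVB/NJ, Zfp740, a zinc finger protein, with 0.14, −0.11 and −0.13, and Lgals3 with −0.64, 0.07 and −0.06. Tmem165, a Golgi manganese transporter, differed by 0.20, −0.20 and −0.20. None passed the limma F test (0 of 13892, smallest adjusted p = 0.997, with 462 at unadjusted p < 0.05). The pairwise differences of the responses also gave 0 genes each: 479 had unadjusted p < 0.05 for DBA/2J minus C57BL/6J (smallest adjusted p = 0.291), 751 for FVB/NJ minus C57BL/6J (0.874) and 359 for FVB/NJ minus DBA/2J (1). On these differences camera called 11, 10 and 8 lists, and 0 with an estimated correlation (smallest adjusted p = 0.693, 0.847 and 0.799) or with fry. An exact permutation test of list scores, chosen after those calls were seen, passed in 0 of 63 cases (smallest adjusted p = 0.386). The smallest exact p in it were 0.011 for immediate early genes, which differed by 0.27 more downwards in DBA/2J than in C57BL/6J, and 0.0122 for ribosomal protein genes, which differed by 0.11 more downwards in FVB/NJ than in C57BL/6J. A list called in 1 strain and not in another was therefore not shown to differ between them.

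Across genes, the fructose differences of the strains were weakly related. Pearson's r was 0.229 (rho 0.229) for C57BL/6J and DBA/2J, 0.0369 (rho −0.0938) for C57BL/6J and FVB/NJ and 0.0585 (rho 0.0669) for DBA/2J and FVB/NJ. By permutation of treatment within each strain on its own, which leaves aside the animal numbers that recur between strains, p was 0.22, 0.71 and 0.73 for r and 0.2, 0.35 and 0.61 for rho, and adjusted p over the 3 pairs 0.66, 0.73 and 0.73 for r and 0.525, 0.525 and 0.61 for rho. Genes are not independent replicates, so these values describe genes only. Without DBA/2J water 5 r was 0.00784 for C57BL/6J and DBA/2J and 0.291 for DBA/2J and FVB/NJ. Genes with unadjusted p < 0.05 in both strains numbered 32 (17 of the same sign, 53.1%), 30 (13, 43.3%) and 48 (45, 93.8%). Independent genes would give 25.8, 27.3 and 22.6, but genes are not independent. In 42, 51 and 35 of 100 regroupings of treatment within strain, the real one included, as many genes were shared. The share of the same sign was as far from even in 93, 81 and 5 of them.

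Genes of appetite control and of fructose handling were read in every group. Agrp averaged 11.1 ± 3.79 on fructose and 9.37 ± 0.821 on water in C57BL/6J, and 12.3 ± 4.55 and 11.1 ± 6.27 in FVB/NJ. Pomc, whose product restrains feeding, averaged 28.6 ± 4.67 and 23.0 ± 3.20 in C57BL/6J, 25.9 ± 5.79 and 19.7 ± 10.3 in DBA/2J and 20.4 ± 7.14 and 21.0 ± 6.17 in FVB/NJ. Npy, a feeding peptide made with Agrp, averaged 62.6 ± 22.9 and 55.0 ± 2.59, 26.5 ± 2.05 and 21.9 ± 8.97, and 78.1 ± 35.1 and 87.6 ± 56.9 in the same order. Cartpt, a satiety peptide, averaged 71.2 ± 4.26 and 62.6 ± 5.18, 89.9 ± 19.9 and 72.8 ± 26.5, and 77.2 ± 13.8 and 74.0 ± 13.1. In the lateral hypothalamus peptides, Hcrt averaged 221 ± 40.5 and 205 ± 42.3, 156 ± 23.6 and 157 ± 31.0, and 176 ± 27.7 and 188 ± 25.4, and Pmch 635 ± 98.3 and 585 ± 77.0, 648 ± 91.3 and 614 ± 108, and 529 ± 116 and 512 ± 86.0. Oxt outside C57BL/6J averaged 379.8 ± 98.3 and 373 ± 141 in DBA/2J and 284 ± 53.7 and 279 ± 50.2 in FVB/NJ, and Avp, vasopressin, 338 ± 32.1 and 340.1 ± 61.1 in C57BL/6J, 374 ± 106 and 471 ± 242 in DBA/2J and 673 ± 200 and 584 ± 91.3 in FVB/NJ. Trh, which drives the thyroid axis, averaged 90.1 ± 5.93 and 74.1 ± 6.12, 69.0 ± 12.5 and 63.7 ± 19.2, and 76.6 ± 9.07 and 72.8 ± 7.03, and Crh, which drives the adrenal axis, 4.41 ± 1.31 and 3.21 ± 0.549, 4 ± 1.1 and 3.26 ± 0.683, and 4.73 ± 0.547 and 5.32 ± 0.343. Slc2a5, the fructose transporter, was near 1 in every group (1.16 ± 0.0628 and 1.33 ± 0.201, 1.08 ± 0.0952 and 1.05 ± 0.140, and 1.32 ± 0.177 and 1.17 ± 0.0377), and Khk, which phosphorylates fructose, averaged 8.11 ± 0.940 and 7.29 ± 0.621, 7.14 ± 0.338 and 6.52 ± 0.355, and 6.65 ± 0.583 and 6.96 ± 0.760. None of these 12 genes passed in any fructose comparison by limma (smallest adjusted p = 0.901, 0.987 and 1 in the 3 strains), and 1, Crh in C57BL/6J, had unadjusted p < 0.05.

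Lists of sugar and fatty acid metabolism were not called on fructose in any strain. Hexose transport and fructose metabolism had medians of 0.0082, −0.033 and −0.0026 in C57BL/6J, DBA/2J and FVB/NJ (18 genes, camera adjusted p = 0.574, 0.31 and 0.854), and fatty acid synthesis 0.0039, 0.0058 and −0.014 (22 genes, adjusted p = 0.909, 0.621 and 0.879). Glycolysis (18 genes) gave adjusted p = 0.931, 0.33 and 0.363, fatty acid oxidation (19 genes) 0.535, 0.399 and 0.893, and appetite and metabolic hormone receptors (29 genes) 0.739, 0.389 and 0.541. For oxidative stress (18 genes) the values were 0.698, 0.389 and 0.295, for inflammation (11 genes) 0.0896, 0.814 and 0.298, and for the interferon response (19 genes) 0.574, 0.266 and 0.469. GABA and glutamate transmission (30 genes) gave 0.581, 0.686 and 0.0954, and monoamine synthesis and transport (13 genes) 0.0995, 0.31 and 0.591. Among cell type markers, neurons gave 0.0678, 0.679 and 0.541, astrocytes 0.0799, 0.572 and 0.591, tanycytes and ependyma 0.627, 0.359 and 0.158, and oligodendrocytes 0.0817, 0.198 and 0.799. Choroid plexus markers gave 0.574, 0.875 and 0.591, pituitary markers 0.627, 0.389 and 0.799, and markers of cortex, hippocampus and amygdala 0.739, 0.418 and 0.949. Mitochondrially encoded mRNAs had 0 of 13 genes in the files and were not tested.

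Many genes differed in measured abundance between the strains in water mice. Per the labels, reads of all strains were aligned to mm10. An effect of this reference on the strain calls was not tested. In DBA/2J against C57BL/6J, Hddc3, a nucleotide hydrolase, averaged 41.4 ± 2.34 and 9.85 ± 0.267 (log2 difference 1.97, adjusted p = 7.66e-18), Stab2 3.92 ± 0.848 and 0.317 ± 0.0395 (1.88, adjusted p = 9.23e-09) and Scd3, a fatty acid desaturase, 4.10 ± 0.171 and 0.848 ± 0.0925 (1.46, adjusted p = 1.01e-09). Lower in DBA/2J were Fggy, a carbohydrate kinase, at 0.0184 against 4.52 ± 0.606 (−2.43, adjusted p = 2.44e-13), and Pttg1, securin, at 2.28 ± 0.780 against 23.1 ± 1.27 (−2.90, adjusted p = 2.03e-10). Single oligodendrocyte and microglia genes were lower as well, with Sox10, the master regulator of oligodendrocytes, at 4.14 ± 0.431 against 10.4 ± 0.559 (−1.15, adjusted p = 1.35e-10) and C1qc, a complement subunit, at 14.6 ± 2.12 against 29.0 ± 3.42 (−0.95, adjusted p = 2.24e-08). Acaca, the enzyme that commits carbon to fatty acid synthesis, averaged 11.1 ± 0.353 and 16.2 ± 1.08 (−0.51, adjusted p = 6.6e-07). Sord, which makes fructose from sorbitol, averaged 7.65 and 11.6 (−0.55, adjusted p = 6.26e-09). Feeding peptides differed: Agrp was lower by −1.41 (adjusted p = 0.0157) and Npy by −1.38 (adjusted p = 0.00973). With the animal number as a block these calls were lost (Agrp −0.93, adjusted p = 0.139, and Npy −1.14, adjusted p = 0.0906). The block leaves C57BL/6J water 1 and DBA/2J water 5 out of the difference, so the loss was not shown to come from the pairing. Agrp was also lost without DBA/2J water 5 alone (−0.97, adjusted p = 0.0649). Adjusted p ranged from 0.00361 to 0.139 for Agrp and from 0.00237 to 0.0906 for Npy in 40 alternatives each. The plain mean of all 3 lane files, not among these, gave adjusted p = 0.000442 for Agrp and 0.00842 for Npy. Of 13892 genes 2738 passed by limma, 1172 higher and 1566 lower, and 2336 with the block.

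The largest differences of that comparison lay in multi-copy genes, whose values are uncertain because reads of near-identical copies cannot be told apart. Rprl3, a ribonuclease P RNA-like gene, averaged 1137 ± 54.5 and 1.61 ± 1.24, and Rpl29 0.780 and 70.1. By gene list, immediate early genes had 8 members higher and 0 lower of 23 (8 adjusted over the list alone), among them Fosl2, an AP-1 subunit, at 2.69 ± 0.719 and 1.33 ± 0.0744 (0.64, adjusted p = 0.0036). Fatty acid synthesis had 1 higher and 8 lower of 22, oligodendrocyte markers 0 and 4 of 16 (5 lower adjusted over the list alone), microglia markers 0 and 3 of 14, and hexose transport 1 and 5 of 18. The direction of the strain counts rested on scaling being applied between mice: with TPM as deposited, which is unscaled, 221 genes were higher and 4456 lower in DBA/2J, 4677 in total, and the median of all genes moved by −0.188. Quantile normalization gave 1279 higher and 1457 lower, and scaled FPKM 1171 and 1570, near the 1172 and 1566 of the main fit.

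In FVB/NJ against C57BL/6J, Gdpd3 (chromosome 7, 126766414 to 126775645), a lysophospholipase D, averaged 11.1 ± 1.80 and 0.439 ± 0.132 (log2 difference 3.06, adjusted p = 3.64e-17), and Gabra2 31.5 ± 1.39 and 7.51 ± 1.08 (1.94, adjusted p = 2.24e-14). Cga, the subunit shared by pituitary glycoprotein hormones, averaged 12.6 ± 7.37 and 0.858 ± 1.42 (2.99, adjusted p = 0.00396). Cga belongs to the pituitary marker list, which had 3 members higher and 0 lower of 9, the others being Lhb and Rbp4. Whether the tissue held differing amounts of pituitary was not tested. Gal, the feeding peptide galanin, averaged 43.7 ± 7.95 and 19.8 ± 3.85 (1.11, adjusted p = 2.28e-05), Crh was higher by 0.60 (adjusted p = 0.00653), and Mc4r, the melanocortin receptor that restrains feeding, averaged 2.26 ± 0.280 and 1.21 ± 0.158 (0.56, adjusted p = 0.000855). Among stress genes Hspa1b, an inducible heat shock protein, averaged 13.5 ± 1.21 and 4.40 ± 0.430 (1.43, adjusted p = 1.14e-05), and Creld2, an endoplasmic reticulum chaperone, 16.4 and 8.83 (0.78, adjusted p = 0.000794). Lower in FVB/NJ were Acadl, a dehydrogenase of fatty acid oxidation, at 5.55 and 12.1 (−1.0, adjusted p = 1.66e-09), and Opalin, a myelin protein, at 5.28 ± 2.97 and 12.3 ± 0.964 (−1.19, adjusted p = 0.000881). Immediate early genes had 13 members higher and 0 lower of 23 (16 adjusted over the list alone), the unfolded protein response 8 and 0 of 21, heat shock 7 and 1 of 13, oligodendrocyte markers 0 and 10 of 16 and microglia markers 2 and 6 of 14. Altogether 3502 genes passed by limma, 1659 higher and 1843 lower. With TPM as deposited these were 358 and 3030, with a median shift of −0.135, and the unfolded protein response list then had a median of −0.038 in place of 0.12. Quantile normalization gave 1829 genes higher and 1748 lower.

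In FVB/NJ against DBA/2J, Fgf1 (chromosome 18, 38838673 to 38918699, overlapping Gm5820), a growth factor that lowers feeding and blood glucose, averaged 5.61 ± 0.525 and 34.5 ± 2.68 (log2 difference −2.42, adjusted p = 1.02e-17), and Specc1, a cytoskeletal protein, 2.18 ± 0.392 and 12.0 ± 0.779 (−2.04, adjusted p = 1.74e-15). Stab2 was lower in FVB/NJ by −2.20 (adjusted p = 8.29e-10). Higher were Fggy at 4.25 and 0.0184 (2.34, adjusted p = 4.39e-13), Neat1, a nuclear noncoding RNA, at 9.23 ± 1.89 and 2.30 ± 0.786 (1.64, adjusted p = 1.45e-05) and Npy by 1.86 (adjusted p = 0.0012). Agrp was higher by 1.48 (adjusted p = 0.0165), a call lost without DBA/2J water 5 (1.04, adjusted p = 0.0727), without FVB/NJ water 2 (1.19, adjusted p = 0.0689) and without FVB/NJ water 8 (1.35, adjusted p = 0.0546), over a range of 0.00476 to 0.119 in 39 alternatives. Slc2a4, the insulin-responsive glucose transporter, averaged 4.24 ± 1.55 and 0.968 ± 0.174 (1.37, adjusted p = 9.42e-08), and Gfap, an astrocyte filament protein, 103 ± 18.9 and 50.2 ± 17.5 (1.07, adjusted p = 0.00155). Ifit3, an interferon-induced antiviral gene, averaged 2.90 ± 0.875 and 10.0 ± 4.99 (−1.43, adjusted p = 0.000421). The interferon response list had 1 member higher and 10 lower of 19 (12 lower adjusted over the list alone), heat shock 6 and 0 of 13, fatty acid synthesis 6 and 2 of 22 and hexose transport 4 and 0 of 18. In total 1655 genes passed by limma, 869 higher and 786 lower, and with TPM as deposited 549 and 335, 884 in all, with a median shift of 0.0552. The 3 strain comparisons share groups and are not independent.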

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

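The tests of this part were chosen after the values were seen, except the meninges covariate, the ribosomal RNA test and the first strain test of DBA/2J water 5, whose predictions preceded their runs. The tests of Glo1, of depth and of the DBA/2J background were each given another criterion after a first one had been read: depth by r alone left the question open, and the first background criterion restated the pattern. A search for single mice far from the other 3 of their group covered 222 groups of 4 values, a set chosen after values were seen. It compares the gap to the nearest mouse with the whole range and found 12 values, in 8 mice, over the 95% critical ratio of Dixon for 4 values, where 11.1 values are expected by chance at 1 in 20.

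Meninges markers and extracellular matrix genes were lower in C57BL/6J fructose mice, and DBA/2J fructose 12 had a meninges score of 2.18 against 2.86 to 2.92 in the other 3 (ratio 0.924). Uneven amounts of meninges on the tissue could explain the matrix genes: over the 20 matrix genes outside the meninges list the median log2 difference went from −0.143 (interquartile range −0.411 to −0.0642, 19 lower) to −0.0195 (−0.0997 to 0.000408, 15 lower) once the score of the 9 meninges genes outside the matrix list was a covariate. An effect of fructose on the meninges was not told apart from this, as the exact p of the meninges score was 0.114. Dissection and a thinner membrane would leave the same mark on bulk RNA. The covariate test fits the first explanation but cannot say why the amounts differed.

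Thalamus markers were high in DBA/2J fructose 10, water 3 and water 5 (scores 4.35, 4.49 and 4.98), across the treatment groups, where the other 5 DBA/2J mice had 3.55 to 3.98. A dissection that took in more thalamus and less hypothalamus is consistent with the relation of thalamus and hypothalamic region scores over the 8 DBA/2J mice (r −0.936, exact p = 0.00119, rho −0.833, exact p = 0.0154, r −0.757 without the 2 farthest, adjusted p = 0.00282 and 0.0342 over 5 relations), and the other 16 mice, with group means removed, had r −0.723 (rho −0.58, permutation p = 0.00169 and 0.0205, r −0.524 without the 2 farthest). Ribosomal RNA left in the library was read by its precursor, which was also high in fructose 10 and water 5 (4463 and 9248) and lower in water 3 (1016). Lars2, described below, was high in fructose 10, water 3 and water 5 (58.2, 239 and 138) against 1.57 to 2.28 in the other 5. Ribosomal RNA other than this precursor was not read, so the precursor value of water 3 decides nothing. Pre-ribosomal RNA was related to the thalamus score (r 0.859, exact p = 0.00813, rho 0.619, exact p = 0.115, r 0.78 without the 2 farthest, adjusted p = 0.0102 and 0.144). The widest thalamus range within a C57BL/6J or FVB/NJ group, all low in that RNA, was 0.811 of the widest within a DBA/2J group, which decides nothing. That water 5 is an inbred C57BL/6J or FVB/NJ mouse was argued against by its Glo1 of 91.8, as those 16 mice had 38.9 to 55.4, whereas a mouse of other or mixed descent stays open, as 70% of its strain genes lay nearest the DBA/2J mean, a share that decides nothing since water 4 had 62.9%. No biological explanation was tested.

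Most DBA/2J mice and C57BL/6J water 2 had more assembled loci without a strand, 28661 per lane file in C57BL/6J water 2 against 13152 to 14867 in the other 3 (ratio 0.889). Deeper sequencing was argued against as the whole cause, because 4 of the 7 libraries lay at or below the median depth of the other 17 (2.52 to 3.25 against 2.00 to 3.41 gigabases per lane file), and r between depth and such loci over 24 mice was 0.21 (permutation p = 0.325, rho 0.0365, permutation p = 0.865, r −0.0757 without the 2 farthest). Unspliced RNA or genomic DNA in the library is a candidate explanation, since the loci rose with the summed TPM of 1456 sensory receptor genes taken as silent in this tissue, strain means removed (r 0.752, permutation p = 4e-05, rho 0.605, permutation p = 0.0022, r 0.493 without the 2 farthest, adjusted p = 0.0002 and 0.011 over 5 relations). A DBA/2J background stays open: 2 DBA/2J mice lay in the range of the other strains, and the other 6 exceeded every mouse of those strains except C57BL/6J water 2.

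Pre-ribosomal RNA was 4463 in DBA/2J fructose 10 against 513.5 to 554 in the other 3 (ratio 0.99), and 9248 in DBA/2J water 5 against 498 to 1016 (ratio 0.941). Lars2, a mitochondrial leucyl-tRNA synthetase, was 58.2 in DBA/2J fructose 10 against 1.57 to 1.90 (ratio 0.994), and 10.8 in FVB/NJ water 1 against 1.74 to 2.97 (ratio 0.864). Its value was 239 in DBA/2J water 3 and 138 in DBA/2J water 5. The extracellular matrix score was 2.58 in DBA/2J water 2 against 2.31 to 2.33 (ratio 0.932). DBA/2J fructose 12 had an endothelial score of 3.46 against 3.62 to 3.63 (ratio 0.918) and a Slc2a5 of 0.938 against 1.12 to 1.14 (ratio 0.907). The pericyte and smooth muscle score was 2.03 in FVB/NJ water 2 against 2.49 to 2.56 (ratio 0.867). A striatum score of 3.67 set DBA/2J fructose 10 apart from 2.935 to 3 (ratio 0.912). Trh was 63.1 in FVB/NJ fructose 6 against 79.3 to 82.0 (ratio 0.86).

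Among genes with unadjusted p < 0.05 in both DBA/2J and FVB/NJ, 93.8% had the same sign of the fructose difference. In 5 of 100 regroupings of treatment within strain the share was as far from even (permutation p = 0.05, adjusted p = 0.15 over the 3 pairs, highest other 98.4), so chance could not be excluded. Shared genes numbered 48, and 35 of 100 regroupings gave as many, up to 310.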

How the results depend on the processing

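Alternatives were written in advance, except the fit without 3 doubted libraries (DBA/2J fructose 10 and water 5, C57BL/6J water 2), the covariates of unstranded loci, meninges and thalamus and the plain mean of all lane files, which were chosen after seeing the data. Counts of fructose genes stayed at 0 in nearly all of them. TPM as deposited, the best lane file and the plain mean of all 3 lane files each gave 1 gene in DBA/2J, Stab2 (adjusted p = 0.000515, 0.0341 and 3.39e-06). Without DBA/2J fructose 12, fructose 9 or water 2 it was 1 gene as well, again Stab2. Array weights gave 1 gene in C57BL/6J, Lgals3 (adjusted p = 0.0341), and leaving out C57BL/6J water 4 gave 2, Lgals3 and Spp1. With no filter beyond TPM above 0 in 4 mice FVB/NJ had 1 gene, Snord123 (log2 difference −0.25, adjusted p = 0.018). The meninges covariate gave 1 gene for the average, Larp1b. Leaving out any 1 mouse, C57BL/6J had 0 to 2 genes, DBA/2J 0 to 1, and FVB/NJ, the average and the interaction 0. Except for the smaller samples, the cause was not tested.

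The plain mean, which includes incomplete lane files, changed most. It gave 11 genes in C57BL/6J, 3 for the interaction (Mirlet7b, Peg3os and Stab2) and 206, 208 and 116 for DBA/2J against C57BL/6J, FVB/NJ against C57BL/6J and FVB/NJ against DBA/2J, and r for DBA/2J and FVB/NJ was −0.179. It changed the sign of 106 of 587 named values in a first run, and was then kept for counts and r alone and left out of the tallies of named values below. Of the values tallied there it kept 152 of 202 for fructose (48 reversed, and Spp1 in C57BL/6J and Stab2 in DBA/2J gained a call), 74 of 316 between strains (212 lost a call and 30 reversed) and 9 of 10 for the interaction, where Stab2 gained a call (adjusted p = 0.015). Missing chromosomes in the incomplete files move these means by construction, but their share in each change was not tested.

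Strain counts were 4677 and 884 with TPM as deposited for DBA/2J against C57BL/6J and FVB/NJ against DBA/2J, and 1561 and 832 with only the 2 groups compared, where fewer mice estimate the spread. Without 1 mouse they ran from 2140 (without C57BL/6J water 4) to 2967 (without DBA/2J water 4), from 2860 to 3881 (without DBA/2J water 5), and from 1327 (without DBA/2J water 3) to 2090 (without DBA/2J water 4). With TPM as deposited, 4 named genes reversed: Tsc1 (−0.00839), Hsp90ab1 (−0.00937) and Eno2 (−0.0281) in DBA/2J against C57BL/6J and Hk1 (−0.00314) in FVB/NJ against C57BL/6J. That setting moves the median of all genes, which accounts for the sign. With the replicate block, which leaves out the 2 mice without a partner, 2336 genes passed in DBA/2J against C57BL/6J in place of 2738. No count with the block is given for another comparison.

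Lists called were 0 in the 3 strains and the average with an estimated correlation, with directional fry and with mixed fry. Without the 3 doubted libraries DBA/2J had 5 lists and r for DBA/2J and FVB/NJ was 0.236. Leaving out 1 mouse, C57BL/6J had 7 (without fructose 10) to 15 lists, DBA/2J 2 (without water 5) to 12, FVB/NJ 3 (without water 9) to 12 and the average 10 to 15. Over genes with unadjusted p < 0.05 in both, r was 0.16 (rho 0.128) for C57BL/6J and DBA/2J, −0.221 (rho 0.0358, of the other sign) for C57BL/6J and FVB/NJ and 0.299 (rho 0.699) for DBA/2J and FVB/NJ. Without 1 mouse r ran from 0.00784 to 0.342 for C57BL/6J and DBA/2J, from −0.0811 to 0.143 for C57BL/6J and FVB/NJ, and from −0.0453 to 0.291 for DBA/2J and FVB/NJ, the ends mostly without DBA/2J water 4 or 5.

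With the plain mean left out, 2912 of 2919 named fructose values kept direction and call in other settings, 4 gained a call and 3 reversed: Bmp4 (0.06) and Vtn (0.0638) in C57BL/6J with the meninges covariate and Lhx9 (0.046) with the thalamus covariate. Without 1 mouse 4842 of 4848 held, 5 gained a call and Amotl1 in DBA/2J reversed (−0.218 to 0.0105, the last without DBA/2J water 5). Interaction values held in 138 of 138, the plain mean again left out, and without 1 mouse in 240 of 240. No fructose or interaction gene passed in the main fit, so a value that held was one still without a call. The interaction has no direction to reverse. Leaving out a mouse of another strain does not change a difference within a strain. These fructose and interaction tallies therefore say little about stability. Strain values held in 4456 of 4799 without the plain mean, with 339 losing a call, and without 1 mouse in 7242 of 7584, with 342 losing one. Group means of the 12 fixed genes held in 207 of 216. The cause was not tested. Depth limits genes near TPM 1 most, and without counts its share is unknown.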

Other observations

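The tests of this part, including how the splits were to be read, were chosen after the results were seen, except the first strain test of DBA/2J water 5. Within a strain, or between 2 water groups, all 35 splits of the 8 mice were fitted, and for the average and the interaction 100 regroupings were drawn, the real one included. For the fructose effect in C57BL/6J, DBA/2J and FVB/NJ the real count was 0 genes, which 35 of 35 splits reach by construction, so these splits say nothing about chance. Their highest other counts were 1, 624 and 20. The same holds for the average (100 of 100 regroupings, highest other 7) and the interaction (100 of 100, highest other 59). For the strain comparisons only 1 of 35 splits, the real one, reached 2738, 3502 and 1655 genes, the highest others being 8, 20 and 67. This is the smallest share that 35 splits can give. Each other split mixes strains within its groups, which widens their spread, so the splits alone cannot exclude chance. For gene lists called by camera chance cannot be excluded: the real 12, 10 and 8 in C57BL/6J, DBA/2J and FVB/NJ were reached in 8, 19 and 22 of 35 splits (highest other 17, 17 and 14), and the 12 of the average in 33 of 100 (highest other 22). The other splits had a median of 9, 10.5 and 8 lists, and the other regroupings of the average a median of 10. Among splits that part the 3 numbered pairs of C57BL/6J and DBA/2J water mice, 8 in all, the highest other was 0 genes.

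A split that calls many genes points to a structure of the samples. The 624-gene split of DBA/2J, 246 genes higher and 378 lower, set fructose 10 and water 2, 3 and 5 against fructose 9, 11 and 12 and water 4. In it thalamus markers were higher (median 0.64, adjusted p = 2.63e-05, and 0.569 with an estimated correlation) and glucocorticoid responsive genes higher (0.48, adjusted p = 9.94e-06, and 0.494 with an estimated correlation). Lower were ribosomal protein genes (−0.13, adjusted p = 1.22e-08, and 0.494 with an estimated correlation), appetite neuropeptides (−0.26, adjusted p = 0.000755, and 0.494 with an estimated correlation) and hypothalamic region markers (−0.30, adjusted p = 9.03e-05, and 0.494 with an estimated correlation), and insulin signalling genes were higher (0.15, adjusted p = 0.00196, and 0.494 with an estimated correlation). This split is the real grouping with fructose 10 and water 4 exchanged, so lists shared with the fructose comparison are partly built in. The 67-gene split of the FVB/NJ and DBA/2J water mice put DBA/2J water 5 with FVB/NJ water 1, 2 and 8, and the next largest, with 35 genes, put DBA/2J water 4 with FVB/NJ water 1, 8 and 9, so such splits were not particular to water 5.

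The strain of DBA/2J water 5 was tested in 3 ways. By the first, 444 of 634 strain genes (70%) lay nearest the DBA/2J mean, between bounds of 50 and 90 set beforehand, and the other 7 DBA/2J mice had 62.9 to 92.7%, so that this measure decided nothing. A narrowed form over 47 genes more than 2-fold apart, chosen after that, gave 43 (91.5%) against 92.9 to 100% in the others and does not replace the first. The last used Glo1, at 91.8 in water 5 and 38.9 to 55.4 in the other strains. Its first form also asked for a value within 2 SD of the other 7 DBA/2J mice (96.8 ± 1.75), which water 5 missed, and that condition was dropped after the value was seen because it bears on mixed descent and not on an inbred mouse of another strain. Gabra2 was 28.9 in water 5 and at most 8.99 in C57BL/6J. In the principal component analysis water 5 stood at 25.02 on the third component, which carried 10.2% of the variance.

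Kiss1, a reproductive neuropeptide precursor, passed adjusted over the list alone in DBA/2J, at 0.900 ± 0.117 on fructose and 0.362 ± 0.275 on water (n = 4 each), in a list that was not called there (camera adjusted p = 0.634). Dlk1 passed in the same way in FVB/NJ, in the pituitary list (camera adjusted p = 0.799).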
